A study of Mus musculus with 36 samples.

How the data were processed

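Total RNA of 36 samples of cultured primary mouse myoblasts was measured. There were 3 samples for each of 12 groups of genotype (WT or Ankrd2 knockout), virus (Ad-Ankrd2 or Ad-GFP) and stage (proliferating, fusing, differentiated). Per the labels' protocols, 50 ng of RNA was labelled with one dye and hybridized to a mouse array of 60-nucleotide probes, 8 arrays to a slide, and cells were infected 20 h before collection. The mice had a mixed strain background, per the labels. The virus of a sample was read from its title, since the characteristic of the Ad-Ankrd2 samples names both viruses.

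The deposited scanner files hold a processed signal intensity for each spot. Per the file headers, the authors made it with Agilent Feature Extraction 10.7.3.1, which subtracted background and removed spatial trends within each array, and did not normalize between arrays. The files also hold mean spot intensity, local background and flags for each spot. The deposited series table holds linear intensities that the authors normalized between arrays by quantiles in the Expander software, per the submitters' processing notes. Those notes say that only arrays passing at least 8 of 9 quality metrics were used. Of the table's columns 34 matched their own array best, while those of KO Ad-Ankrd2 fusing replicates 1 and 2 matched each other's array. The table was used only as an alternative.

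Control spots were left out, and spots marked as outliers in the files were set aside. The log2 processed signals of repeated spots were averaged for each of 55681 probes and quantile normalized over the 36 arrays. Gene names came from the annotation table through the accession for 26425 probes, and from the file's own gene name for 29256. Probe positions are those of the files (mm9). Of the probes of a gene, the one with the highest mean over all arrays stood for it, which gave 35696 names, 10698 of them with over 1 probe. A gene was tested in a comparison if its probe was well above background on all arrays of at least 1 of its groups, counting groups with at least 2 arrays not set aside. Over all groups 23305 genes were so detected, 14686 of them named by a symbol. Where 1 group was not above background, the change is given as at least the fold over that group's background level.

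Changes were tested with limma 3.58.1 in R 4.3.3, in 1 linear model of 12 group means over all 36 arrays, with a moderated spread for each gene (24 residual degrees of freedom). There were 14 pairwise comparisons and 3 differences of differences. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05. Changes are log2 values with their standard errors. Of a set of 31 gene lists of pathways and cell types, fixed before the values were seen, and the genes within 10 Mb of Ankrd2, each was tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. P-values were adjusted over the lists of a comparison. On the array were 738 of 745 list genes. Lists for hindlimb position, forelimb position and neutrophil granules were added after the values were seen and were not tested as lists.

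The text names genes by a rule set in advance: Ankrd2, Ankrd1 and Ankrd23; the 10 largest rises and falls among symbol-named genes past the threshold whose arrays separate fully; and the 4 members of each list with the smallest adjusted p. For the differences of differences full separation was not required. The text takes those it discusses from these. Other genes are said to be chosen after their values were seen.

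The replicate number was checked for pairing through the correlation of deviations from the group means of arrays with the same number. It was over 0.1 in every pair for KO against WT in proliferating cells with either virus (lowest 0.16 and 0.21), and for Ad-Ankrd2 against Ad-GFP in proliferating WT (0.51), fusing WT (0.47), proliferating KO (0.55) and differentiated KO cells (0.34). The 10% of fully separated genes by chance is that of independent arrays, which these are not. Any pairing comes from this check and not from the labels, and a slide shared by arrays of the same number could give it too. The slide of each array, on 6 slides, was read from the files.

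Alternatives tried were a 75th percentile shift in place of quantile normalization, normexp background correction with an offset of 50, the authors' table, no filter on dim probes, one gene set for all comparisons, outlier spots kept, only the arrays compared, replicate number as a block, culture as a random block, slide as a block (random where no slide is shared), a mean-variance trend, the mean of a gene's probes, a fold of at least 2, and leaving out each array in turn. Those added after the values were seen were the replicate number as a block within the stage, the replicate 3 arrays of a stage left out together, and differences within single slides. In these alternatives the lists were tested on the moderated t values. Figures were drawn with matplotlib 3.10.9.

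The analysis was tested on data simulated from the arrays, with 100 genes seeded at each of 2 sizes. Of genes changed 2-fold, 61% were recovered for fusing against proliferating, 62% for KO against WT in proliferating and 55% in differentiated Ad-GFP cells, 46% for Ad-Ankrd2 against Ad-GFP in WT and 52% in KO fusing cells, and 26% and 19% for the differences of differences in proliferating and differentiated cells. Of genes changed 4-fold it was 93%, 93%, 92%, 96%, 90%, 76% and 66%. Between 5 and 12 genes per comparison were called falsely. The simulated arrays varied independently, while the real ones had a consensus correlation within slides of 0.559. These shares and false calls are therefore those of independent arrays, and those of the real arrays may differ.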

Results

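Gene expression was measured on one-colour mouse microarrays in primary myoblasts, the muscle precursor cells, taken from the limbs of pups aged 2 to 3 days. The pups were wild type (WT) or carried a knockout of Ankrd2 (KO), the gene of a muscle ankyrin repeat protein found at the sarcomere and in the nucleus. Cultures were infected with an adenovirus carrying HA-tagged Ankrd2 (Ad-Ankrd2) or with one carrying green fluorescent protein (Ad-GFP). Cells were collected while proliferating, while fusing after 24 h in differentiation medium, and when differentiated after 96 h in that medium. Each of the 12 groups had 3 arrays. The protocol places infection 20 h before collection, but labels of the 3 WT Ad-GFP differentiated samples give 96 h, which enters each of their comparisons. On each array the 75th percentile of the processed signal lay between 128 and 349 (median 211), and between 47.1% and 62.3% of the probes were well above background (median 52.6%). The number of arrays limits the precision. The arrays lay on 6 slides, and groups were spread unevenly over them. All 6 WT differentiated arrays were on slide 5, WT and KO proliferating arrays met only on slide 6, and WT and KO fusing arrays met only on slide 4.

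Ankrd2 itself was followed through a single probe on chromosome 19 at 42118566 to 42118625 of the mm9 build. In Ad-Ankrd2 cultures Ankrd2 signal was far above that of Ad-GFP cultures at every stage and in both genotypes: the lowest of 18 Ad-Ankrd2 arrays stood at 9.82 on the log2 scale and the highest of 18 Ad-GFP arrays at 8.35. In WT cells with Ad-GFP the mean was 4.97 ± 0.71 (SD, n = 3 arrays) in proliferating, 7.71 ± 0.96 in fusing and 7.26 ± 0.26 in differentiated cells. In KO cells with Ad-GFP it was 5.99 ± 0.67, 6.12 ± 0.43 and 7.34 ± 0.28 (SD, n = 3 arrays each). The difference between KO and WT with Ad-GFP was 1.02 ± 0.82 (SE) in proliferating, -1.59 ± 0.82 in fusing and 0.08 ± 0.82 in differentiated cells, none of which passed in limma (adjusted p = 0.561, 0.537 and 0.957). With slide as a block the proliferating difference was -0.55 and the differentiated one -0.41, and within slide 6 the proliferating one was -0.24. The files do not say which part of the gene the knockout removes, so the probe cannot check the genotype. With Ad-Ankrd2 the level was 15.79 ± 0.64 in WT and 13.34 ± 2.27 in KO proliferating cells (SD, n = 3 arrays each). This difference of -2.46 ± 0.82 (SE) did not pass (adjusted p = 0.19). KO replicate 3 stood at 10.74, the others at 14.95 and 14.33, and without it the difference was -1.16 (adjusted p = 0.514). It passed with slide as a block (-4.03, adjusted p = 0.00952), which rests on the same array, the only KO Ad-Ankrd2 one on slide 6.

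**Figure D1:**
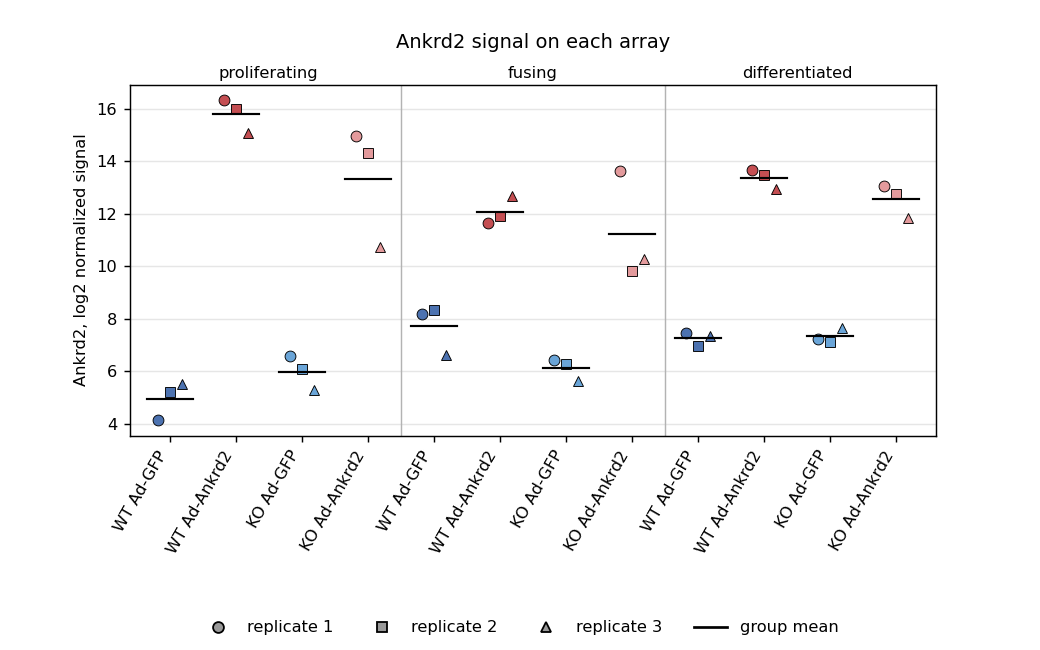
Ankrd2 signal (log2 normalized signal, vertical axis) on each of the 36 arrays, by genotype, virus and stage, with symbols for the replicate number and a line at the mean of each group. The 18 Ad-Ankrd2 arrays lie between 9.82 and 16.32 and the 18 Ad-GFP arrays between 4.17 and 8.35.

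The first step of differentiation was read from WT Ad-GFP cultures, fusing against proliferating. None of the 11 lists called in it held with an estimated correlation. Chl1, a cell adhesion molecule of the nervous system, rose by 8.51 ± 1.66 log2 (SE, 3 against 3 arrays, adjusted p = 0.00104), at least 118-fold. Lbp, which binds bacterial lipopolysaccharide, rose by 5.07 ± 0.53 (adjusted p = 1.27e-06), and the hypoxia-responsive genes Ndufa4l2 and Car9 by 4.99 ± 0.41 and 4.96 ± 0.44 (adjusted p = 3.6e-08 and 1.03e-07). Ankrd2 rose by 2.74 ± 0.82 (adjusted p = 0.023), and its relative Ankrd1 by 0.77 ± 0.23 (adjusted p = 0.0238). Of the largest falls, the prolactin family gene Prl2c5 fell by 4.85 ± 0.8, Mmp10, a matrix metalloproteinase, by 3.64 ± 0.53 (at least 8.12-fold) and the renin gene Ren1 by 3.61 ± 0.34 (adjusted p = 0.00022, 5.87e-05 and 2.25e-07).

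In the gene lists for this step, 20 of 33 fibroblast and matrix genes rose and 1 fell (22 and 1 adjusted over the list), among them Col1a2 by 1.79 ± 0.3 and Mfap4, a microfibril protein, by 3.42 ± 0.58. The list was called by camera (median 1.25, adjusted p = 3.69e-12) and had an adjusted p = 0.201 with an estimated correlation. Of 23 cholesterol genes 15 rose (22 adjusted over the list), with Stard4 at 1.41 ± 0.23, Tm7sf2 at 2.34 ± 0.42 and Lss at 1.39 ± 0.3. The list median was 1.11 (adjusted p = 1.07e-11, and 0.389 with estimated correlation). Complement gave 7 rises of 12 (7 adjusted over the list), including C3 at 3.08 ± 0.47 and Cfb at 2.2 ± 0.35. Its median was 2.32 (adjusted p = 1.74e-05, and 0.389 with estimated correlation). Growth factor genes rose in 12 of 25 cases (13 rose and 3 fell adjusted over the list), with Igfbp4 at 3.5 ± 0.56, the imprinted H19 at 1.53 ± 0.2 and Igf2 at 1.41 ± 0.31. Members of the list had a median of 0.73 (adjusted p = 0.000409, and 0.201 with estimated correlation). Sarcomere genes rose in 5 of 32 cases (13 adjusted over the list), such as Actc1 at 2.19 ± 0.54 and Tnni2 at 2.69 ± 0.73. The median change was 1.88 (adjusted p = 1.76e-06, and 0.674 with estimated correlation). Among 37 cell cycle genes 4 fell (1 adjusted over the list), Ccne1 by 1.54 ± 0.26. Over the list the median was -0.68 (adjusted p = 1.74e-05, and 0.674 with estimated correlation). Heat shock genes fell in 8 of 19 cases and rose in 2 (9 and 4 adjusted over the list), with Hsp90aa1 down by 1.11 ± 0.16. As a list they had a median of -0.38 (adjusted p = 0.00687, and 0.674 with estimated correlation). None of 19 leukocyte genes passed (median -1.07).

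In this first step 3163 of 20320 genes changed, 1906 upward and 1257 downward, and 28.9% of the tested genes separated the arrays of both groups fully, where chance gives 10%. These groups share no slide, and with slide as a random block 4395 genes passed but Ankrd2 and Ankrd1 did not (adjusted p = 0.108 and 0.0842). Leaving out 1 proliferating array gave 1274 (replicate 1) or 1751 (replicate 2), leaving out fusing replicate 2 gave 1838, leaving out all proliferating replicate 3 arrays gave 5836, and the 6 arrays alone gave 361. The genes Ankrd2, Ankrd1, Actc1 and Tnni2 each lost the call when some single array was left out, and Ankrd2 did not pass under normexp correction (1.41, adjusted p = 0.208) or in the authors' table (0.0809).

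The second step was read as differentiated against fusing in WT Ad-GFP cultures. There the adipocyte gene mean went from 7 to 10.72 and the hindlimb one from 7.78 to 3.13. KO Ad-GFP cultures did not share this (7.34 to 6.99 and 7.65 to 7.54). Cidec, a lipid droplet protein of fat cells, rose by 8.18 ± 0.83 log2 (SE, 3 against 3 arrays, adjusted p = 1.73e-07), the adipokine genes Retn and Adipoq by 7.27 ± 0.83 and 6.36 ± 1.18, and Gpd1, an enzyme of glycerol synthesis, by 6.57 ± 1.02 (adjusted p = 1.17e-06, 0.000576 and 9.01e-05). S100a8 and S100a9, the calprotectin genes abundant in neutrophils, fell by 6.26 ± 1.19 and 6.36 ± 1.2, and Stfa1, a cystatin of myeloid cells, by 7.56 ± 1.31 (adjusted p = 0.000682, 0.000675 and 0.00027). Pitx1, the transcription factor that sets hindlimb identity (chromosome 13, 55926417 to 55926476 of mm9), fell by 6.58 ± 0.29 (adjusted p = 6.51e-15). Of the muscle genes, Myod1 fell by 2.3 ± 0.35, Myf6 rose by 2.93 ± 0.62 and the fast myosin gene Myh2 rose by 4.59 ± 0.51 (adjusted p = 7.23e-05, 0.00179 and 8.91e-07).

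By list, 16 of 17 adipocyte genes rose in this second step (17 adjusted over the list), with a median of 3.25 (adjusted p = 1.5e-20, and 0.00891 with estimated correlation). Cholesterol genes fell in 19 of 23 cases (19 adjusted over the list). The list as a whole had a median of -1.09 (adjusted p = 3.19e-11, and 0.443 with estimated correlation). Of 37 cell cycle genes 17 fell (20 adjusted over the list), such as Cenpa by 2.15 ± 0.44 and Ccnb1 by 1.98 ± 0.47. Across its members the median was -1.24 (adjusted p = 5.25e-08, and 0.782 with estimated correlation). Sarcomere genes rose in 4 of 36 cases (4 adjusted over the list), with an adjusted p = 0.0112, and 0.782 with an estimated correlation. The TGF-beta and BMP list had 7 falls among 25 (7 adjusted over the list), Id1 by 2.47 ± 0.38 and Id2 by 1.99 ± 0.29 (adjusted p = 0.0274, and 0.261 with estimated correlation). With slide as a random block the cell cycle, sarcomere and TGF-beta lists lost their calls (adjusted p = 0.0667, 0.124 and 0.0838), as did Cenpa and Ccnb1 (0.117 and 0.185).

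Markers of other cell types moved with this second step. Leukocyte genes rose in 5 of 21 cases (5 adjusted over the list), Aif1 by 3.42 ± 0.9 (median 0.79, adjusted p = 0.0482, and 0.782 with estimated correlation), and the Schwann cell factor Sox10 rose by 1.77 ± 0.32. In lists made after the values were seen, 5 of 9 neutrophil granule genes fell (median -3.23), and all 5 hindlimb position genes fell (Pitx1, Tbx4, Hoxc9, Hoxc10 and Hoxc11, median -4.15). Of 37 cytokine and chemokine genes 8 fell and 3 rose (8 and 3 adjusted over the list), with Cxcl3 down by 4.39 ± 0.63, Il1b by 4.07 ± 0.7 and Il6 by 3.08 ± 0.54. Ankrd23, the third member of the family, rose by 2.4 ± 0.64 (adjusted p = 0.00907), and Ankrd1 fell by 0.79 ± 0.23 (adjusted p = 0.0152), while Ankrd2 differed by -0.46 ± 0.82 (adjusted p = 0.713).

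In the second step 5006 of 21870 genes changed, 2352 upward and 2654 downward (1989 and 4148 after a 75th percentile shift), and 48.7% of the tested genes were fully separated, against 10% by chance. The groups share no slide, and with slide as a random block 1520 genes passed but Ankrd23 and Ankrd1 did not (adjusted p = 0.231 and 0.0912). Leaving out fusing replicate 1 or 2 gave 2682 or 2540, differentiated replicate 1, 2 or 3 gave 3240, 3260 or 3246, and Ankrd1 lost the call without some single array.

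The effect of the knockout without added Ankrd2 was read from Ad-GFP cultures. In proliferating cells Nrxn2, a synaptic adhesion molecule, was lower in KO than in WT by 2.45 ± 0.36 log2 (SE, 3 against 3 arrays, adjusted p = 0.00195) and Arntl2, a clock transcription factor, by 1.59 ± 0.23 (adjusted p = 0.00191). Ren1 was lower by 2.05 ± 0.34 (adjusted p = 0.00501). Kera, a matrix keratan sulfate proteoglycan, was higher by 3.16 ± 0.64 (at least 3.37-fold, adjusted p = 0.0201). Matrix genes rose in 3 of 33 cases (5 rose and 1 fell adjusted over the list), namely Lox, a collagen cross-linking enzyme, by 1.44 ± 0.28, Pdgfrl by 1.11 ± 0.23 and Col1a1 by 1.42 ± 0.34 (adjusted p = 0.018, 0.0254 and 0.0457). Their median was 0.52 (adjusted p = 6.83e-05, and 0.512 with estimated correlation), 0.14 with slide as a block (adjusted p = 0.178) and 0.02 within slide 6. Of 39 interferon genes 1 fell (16 adjusted over the list), the RNA sensor Tlr3 by 2.45 ± 0.53 (adjusted p = 0.0274). That list had a median of -0.77 (adjusted p = 3.78e-12, and 0.512 with estimated correlation), -1.73 with slide as a block and -1.95 within slide 6. Cholesterol genes had 0 of 23 passing (2 rose adjusted over the list) and a median of 0.43 (adjusted p = 0.00196, and 0.747 with estimated correlation), 0.47 with slide as a block and 0.55 within slide 6. No leukocyte gene of 20 passed (median 0.37, and 0.89 with slide as a block).

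In this comparison 153 of 19767 genes changed, 70 upward and 83 downward, and 15.2% of the tested genes were fully separated, against 10% by chance. The count was 232 with replicate as a block, 672 with it as a block within the stage, 100 after a 75th percentile shift, 246 after normexp correction and 0 in the 6 arrays alone. With slide as a block it was 2622, resting on 1 array of each group on slide 6. Leaving out KO replicate 1 or 3 gave 12 or 300, leaving out WT replicate 1, 2 or 3 gave 9, 21 or 1248, and leaving out both replicate 3 arrays gave 2369. Of the 8 genes named only Nrxn2 and Arntl2 kept the call whichever array was left out. With slide as a block Lox and Col1a1 did not pass (0.71, adjusted p = 0.0659, and 0.19, adjusted p = 0.634), and Pdgfrl was 0.41. Within slide 6 Lox (0.88), Pdgfrl (0.43) and Col1a1 (-0.04) did not pass (adjusted p = 0.0838, 0.0533 and 0.949), and under normexp correction Kera and Tlr3 did not pass (adjusted p = 0.122 and 0.0936). Nor did Tlr3 in the authors' table (0.248), or Col1a1 with no filter on dim probes or one gene set for all comparisons (0.063 and 0.0515).

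In fusing cells with Ad-GFP few genes differed between KO and WT. Sdc4, a cell surface heparan sulfate proteoglycan of satellite cells, was lower in KO by 2.37 ± 0.19 log2 (SE, 3 against 3 arrays, adjusted p = 6.9e-08), and was -2.3 with slide as a block. Pdgfrl was higher by 1.26 ± 0.23 (adjusted p = 0.0392), the desmosome gene Dsp by 2.36 ± 0.42 (at least 1.81-fold, adjusted p = 0.0222) and the complement factor gene Cfi by 2.01 ± 0.34 (at least 1.13-fold, adjusted p = 0.0161). Prl2c1 was lower by 1 ± 0.16 (adjusted p = 0.0111). No member passed in the cell cycle (37 genes), cytokine (37) or cholesterol (23) lists. Camera placed cell cycle genes lower (median -0.81, adjusted p = 5.02e-11) and cholesterol genes higher (median 0.4, adjusted p = 0.000304), each with an adjusted p = 0.912 with an estimated correlation, and both medians had the opposite sign with slide as a block (0.44 and -0.2) and within slide 4 (0.57 and -0.32). Cytokine genes had a median of -0.45 (adjusted p = 0.000387, and 0.912 with estimated correlation), 0.09 with slide as a block and -0.27 within slide 4.

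Here 8 of 21511 genes changed, 5 upward and 3 downward (9 and 9 after normexp correction, 4 and 10 in the authors' table), and 11.4% of the tested genes were fully separated, against 10% by chance. The count was 80 with replicate as a block, 99 with it within the stage, 56 with slide as a block, 58 within slide 4 (2 arrays against 1), 15 with culture as a random block, 5 after a 75th percentile shift, 32 with no filter on dim probes, 16 for the mean of a gene's probes and 0 in the 6 arrays alone. Without KO replicate 1, 2 or 3 it was 18, 1 or 2, without WT replicate 1, 2 or 3 it was 1, 1 or 704, and only Sdc4 kept the call in each of these. Dsp and Prl2c1 did not pass with slide as a block (adjusted p = 0.136 and 0.171), and within slide 4 Dsp, Cfi and Prl2c1 did not (0.396, 0.137 and 0.196). After a 75th percentile shift Pdgfrl and Dsp did not (both 0.0926), and Cfi did not under normexp correction (0.251).

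In differentiated Ad-GFP cells the adipocyte and Schwann lists were lower in KO than in WT, and held with estimated correlation. Leukocyte, cytokine and cholesterol lists were higher but did not hold. S100a8 and S100a9 were higher by 9.01 ± 1.19 and 9.3 ± 1.2 log2 (SE, 3 against 3 arrays, adjusted p = 8.69e-06 and 6.94e-06), Stfa1 by 10.17 ± 1.31, the neutrophil granule gene Ngp by 8.25 ± 1.65 (at least 122-fold) and Arg1, an arginase of myeloid cells, by 8.78 ± 0.87 (at least 150-fold; adjusted p = 6.37e-06, 0.00122 and 1.27e-07). Cidec was lower by 8.14 ± 0.83 (at least 74.9-fold), Retn by 7.1 ± 0.83 and Adipoq by 6.1 ± 1.18 (adjusted p = 1.88e-07, 1.64e-06 and 0.000861). Adipocyte genes fell in 16 of 17 cases (16 adjusted over the list), including Pparg, the master regulator of fat cells, by 2.78 ± 0.26. For the list the median was -2.78 (adjusted p = 7.27e-21, and 0.0082 with estimated correlation). Schwann and neural genes fell in 4 of 15 cases (6 adjusted over the list), with Sox10 at -2.22 ± 0.32 and Ngfr at -4.63 ± 0.7. The list median was -0.65 (adjusted p = 0.00572, and 0.0408 with estimated correlation). Leukocyte genes rose in 12 of 21 cases (16 adjusted over the list), with Csf1r at 1.95 ± 0.47, Ptprc at 2.99 ± 0.77 and H2-Ab1 at 3.81 ± 0.78. The list median was 2.36 (adjusted p = 3.32e-07, and 0.426 with estimated correlation).

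Beside these leukocyte genes, cytokine genes rose in 16 of 38 cases and fell in 1 (17 and 2 adjusted over the list), with Il1b at 7.99 ± 0.7, Il1a at 6.4 ± 0.71 (at least 27.8-fold) and Cxcl3 at 7.19 ± 0.63. Its median was 0.9 (adjusted p = 1.74e-06, and 0.261 with estimated correlation). NF-kB components and feedback genes rose in 9 of 23 cases (9 adjusted over the list), with Traf1 at 3.5 ± 0.55 and Nfkb1 at 1.06 ± 0.28. Members of the list had a median of 0.7 (adjusted p = 1.98e-05, and 0.261 with estimated correlation). Cholesterol genes rose in 20 of 23 cases (20 adjusted over the list), Stard4 by 2.02 ± 0.23. The median change was 1.51 (adjusted p = 1.9e-20, and 0.0785 with estimated correlation). Oxidative stress genes rose in 11 of 22 cases (12 adjusted over the list), the cystine transporter Slc7a11 by 3.49 ± 0.49 and the quinone reductase Nqo1 by 2.62 ± 0.55. Over the list the median was 1.09 (adjusted p = 6.17e-06, and 0.179 with estimated correlation). In the lists made after the values were seen, 8 of 10 neutrophil granule genes (median 5.76) and all 5 hindlimb position genes (median 4.37) were higher in KO. The mean of the hindlimb genes was 3.13 ± 0.15 in the WT and 7.54 ± 0.03 in the KO arrays (SD, n = 3 arrays each), and between 7.37 and 7.9 in every group of the earlier stages.

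Here 3805 of 21774 genes changed, 2076 upward and 1729 downward, and 45.8% of the tested genes were fully separated, against 10% by chance. The groups share no slide, and their labels give 96 h (WT) and 20 h (KO) of infection. Genotype is told apart from neither here. With slide as a random block 3098 genes passed but Nfkb1 did not (0.67, adjusted p = 0.0861). Under it the list medians were 1.3 for leukocyte (Ptprc 1.81, Csf1r 1.3), -0.29 for Schwann and neural, 0.27 for NF-kB, 1.04 for cytokine, 0.98 for oxidative stress, 1.79 for cholesterol and -3.14 for adipocyte genes. Leaving out KO replicate 1 or 2 gave 1910 or 2210, WT replicate 1, 2 or 3 gave 2254, 2226 or 2277, and of the 22 genes named only Nfkb1 lost the call without some single array.

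**Figure D2:**
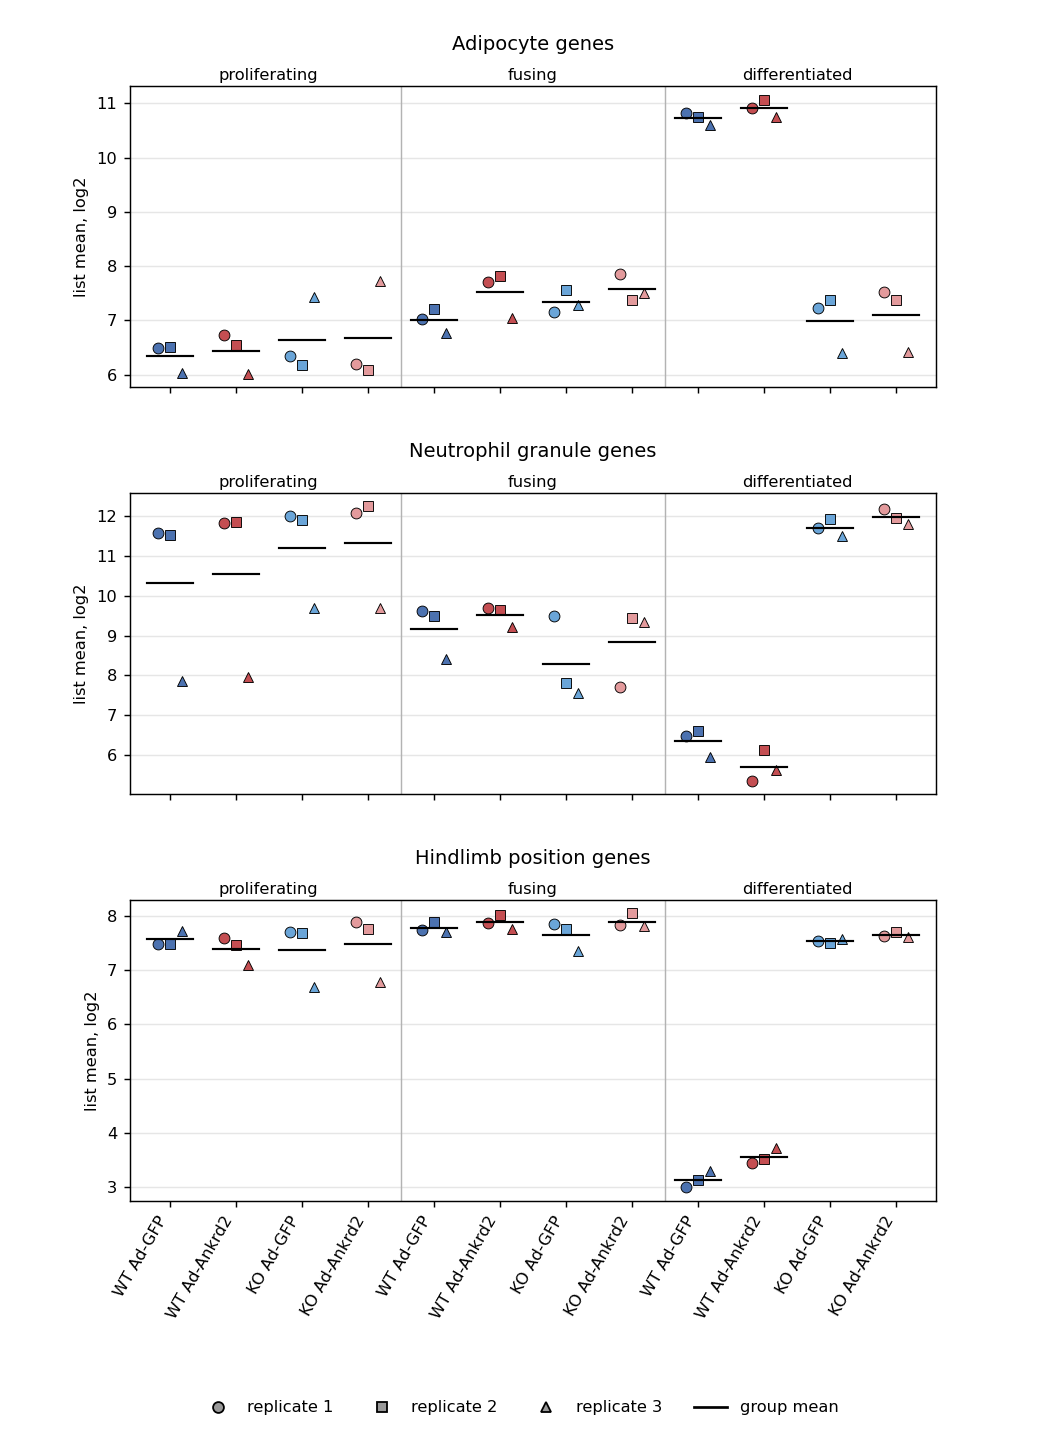
Mean log2 normalized signal (vertical axes) of adipocyte, neutrophil granule and hindlimb position genes on each of the 36 arrays, by genotype, virus and stage, with symbols for the replicate number and lines at the means of the groups. The 6 WT differentiated arrays stand apart in all 3 panels.

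KO and WT cells were also compared when both had received Ad-Ankrd2. In proliferating cells Csf2, the granulocyte and macrophage growth factor gene, was lower in KO than in WT by 4.1 ± 0.63 log2 (at least 5.96-fold; SE, 3 against 3 arrays, adjusted p = 0.00258), Cxcl5, a neutrophil chemoattractant, by 1.25 ± 0.25 (adjusted p = 0.0305), and Mmp3 by 1.49 ± 0.32 (adjusted p = 0.0377). Arntl2 was again lower, by 2.04 ± 0.23 (adjusted p = 3.67e-05). Kera was higher by 3.11 ± 0.64 (at least 5.21-fold, adjusted p = 0.0327), Megf6 by 2.43 ± 0.34 (adjusted p = 0.00117) and Pdgfrl by 1.21 ± 0.23 (adjusted p = 0.0229). Of 37 cytokine genes 2 fell (12 adjusted over the list), with a median of -0.69 (adjusted p = 2.3e-09, and 0.149 with estimated correlation), -1.41 with slide as a block and -1.61 within slide 6. NF-kB genes had 0 of 23 passing (5 fell adjusted over the list) and a median of -0.51 (adjusted p = 1.26e-08, and 0.149 with estimated correlation), -0.48 with slide as a block and -0.75 within slide 6. None of 39 interferon genes passed (0 adjusted over the list), with a median of -0.57 (adjusted p = 4.85e-07, and 0.57 with estimated correlation), -1.4 with slide as a block and -1.14 within slide 6. Cholesterol genes had 0 of 23 passing (2 rose adjusted over the list) and a median of 0.54 (adjusted p = 5.51e-07, and 0.447 with estimated correlation), 0.68 with slide as a block and 0.74 within slide 6.

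Here 64 of 20382 genes changed, 24 upward and 40 downward (22 and 18 after a 75th percentile shift), and 18.1% of the tested genes were fully separated, against 10% by chance. The count was 98 with replicate as a block, 502 with it within the stage, 3566 with slide as a block, 2195 within slide 6 (1 array against 1), 153 after normexp correction, 102 in the authors' table and 0 in the 6 arrays alone. Without KO replicate 1 or 2 it was 12 or 16, without WT replicate 1, 2 or 3 it was 20, 12 or 223, and without both replicate 3 arrays 878. Genes that kept the call whichever array was left out were Csf2, Megf6 and Arntl2. Kera did not pass under normexp correction (adjusted p = 0.104), Megf6 and Kera did not in the authors' table (0.118 and 0.197), and Cxcl5 and Mmp3 did not after a 75th percentile shift (0.0967 and 0.0709). With both viruses 15 genes rose and 11 fell, in cultures that share slides and deviate together by replicate number.

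In fusing cells with Ad-Ankrd2, 4 chemokine genes and Sdc4 were lower in KO than in WT. Cxcl1 was lower by 3.19 ± 0.44 log2 (SE, 3 against 3 arrays, adjusted p = 0.000687), Cxcl5 by 2.38 ± 0.25 (adjusted p = 6.75e-06), and the monocyte chemoattractant genes Ccl2 and Ccl7 by 2.03 ± 0.32 and 1.54 ± 0.28 (adjusted p = 0.0063 and 0.0172). Sdc4 was lower by 2.43 ± 0.19 (adjusted p = 4.05e-08), and Pdgfrl was higher by 1.13 ± 0.23 (adjusted p = 0.0469). Those 4 chemokine genes were the ones that fell among 35 cytokine genes (11 adjusted over the list), with a median of -0.78 (adjusted p = 1.33e-14, and 0.127 with estimated correlation), -0.42 with slide as a block and -0.16 within slide 4. Of 23 NF-kB genes 1 fell (9 fell and 1 rose adjusted over the list), the inhibitor gene Nfkbia by 1.55 ± 0.31. The list median was -0.39 (adjusted p = 6.13e-08, and 0.297 with estimated correlation), -0.32 with slide as a block and -0.27 within slide 4. None of 38 interferon genes passed (0 adjusted over the list), with a median of -0.71 (adjusted p = 1e-12, and 0.965 with estimated correlation), -0.67 with slide as a block and -0.5 within slide 4. Cholesterol genes, none of 23 passing (0 adjusted over the list), had a median of 0.37 (adjusted p = 0.00133, and 0.965 with estimated correlation), -0.21 with slide as a block and -0.14 within slide 4.

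Here 29 of 21333 genes changed, 10 upward and 19 downward (24 and 22 after normexp correction), and 16.7% of the tested genes were fully separated, against 10% by chance. The count was 84 with slide as a block, 48 within slide 4 (3 arrays against 1) and 1 in the 6 arrays alone. Without KO replicate 2 or 3 it was 3, without WT replicate 1 or 2 also 3 and without WT replicate 3 it was 788, and Cxcl1, Cxcl5 and Sdc4 kept the call in each of these. Ccl7 and Nfkbia did not pass with slide as a block (adjusted p = 0.0845 and 0.184), nor within slide 4 (-0.71 and -0.41), where Ccl2 did not either (-0.96, adjusted p = 0.167), and Nfkbia and Pdgfrl did not after a 75th percentile shift (0.0507 and 0.13) or with no filter on dim probes (0.0571 and 0.0613).

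In differentiated cells with Ad-Ankrd2, the difference between KO and WT followed that of the Ad-GFP cultures. Stfa1 was higher in KO by 10.71 ± 1.31 log2 (SE, 3 against 3 arrays, adjusted p = 2.51e-06), S100a8 by 9.94 ± 1.19, S100a9 by 10.38 ± 1.2, the neutrophil lactoferrin gene Ltf by 9.25 ± 1.61 (at least 253-fold) and Ngp by 8.78 ± 1.65 (at least 155-fold). Cidec was lower by 8.18 ± 0.83 (at least 86-fold, adjusted p = 1.63e-07), Adipoq by 6.03 ± 1.18 and Pparg by 2.86 ± 0.26. Of 17 adipocyte genes 16 fell (16 adjusted over the list), with a median of -2.94 (adjusted p = 3.43e-21, and 0.00753 with estimated correlation), -3.54 with slide as a block and -3.45 within slide 5. Schwann and neural genes fell in 5 of 15 cases (8 adjusted over the list), Sox10 by 2.35 ± 0.32. Its median was -0.94 (adjusted p = 0.00186, and 0.0219 with estimated correlation), -0.27 with slide as a block and -0.38 within slide 5. Leukocyte genes rose in 15 of 21 cases (18 rose and 1 fell adjusted over the list), with a median of 2.54 (adjusted p = 1.46e-09, and 0.24 with estimated correlation), 1.19 with slide as a block and 1.3 within slide 5. As with Ad-GFP, 9 of 10 neutrophil granule genes (median 6.58) and all 5 hindlimb position genes (median 3.94) were higher in KO.

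Beside these leukocyte genes, 25 of 38 cytokine genes rose and 1 fell (26 and 1 adjusted over the list), with Cxcl5 at 2.38 ± 0.25, Il1b at 6.64 ± 0.7 (at least 34.1-fold) and Ccl5 at 4.38 ± 0.57. As a list they had a median of 2.13 (adjusted p = 4.59e-13, and 0.0558 with estimated correlation). Their median was 1.57 with slide as a block and 1.51 within slide 5. NF-kB genes rose in 15 of 23 cases (17 adjusted over the list), Traf1 by 4.08 ± 0.55 and Birc3 by 2.25 ± 0.33. Members of the list had a median of 0.92 (adjusted p = 1.4e-11, and 0.0508 with estimated correlation), 0.5 with slide as a block and 0.6 within slide 5. Interferon genes rose in 25 of 41 cases (34 adjusted over the list), Irf7 by 2.84 ± 0.5. The median change was 1.16 (adjusted p = 7.59e-17, and 0.21 with estimated correlation), 0.79 with slide as a block and 0.55 within slide 5. Antigen presentation genes rose in 13 of 18 cases (14 adjusted over the list), the immunoproteasome gene Psmb8 by 1.36 ± 0.21. Over the list the median was 1.06 (adjusted p = 2.88e-09, and 0.151 with estimated correlation), 0.46 with slide as a block and 0.35 within slide 5. Cholesterol genes rose in 19 of 23 cases (20 rose and 1 fell adjusted over the list). As a list they had a median of 1.57 (adjusted p = 4.9e-17, and 0.0682 with estimated correlation), 1.87 with slide as a block and 1.9 within slide 5.

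In differentiated Ad-Ankrd2 cells 4121 of 22083 genes changed, 2153 upward and 1968 downward, and 37.9% of the tested genes were fully separated, against 10% by chance. With slide as a block 4399 genes passed, and within slide 5, which holds 1 KO and 3 WT arrays, 3703 did. Leaving out KO replicate 1, 2 or 3 gave 2185, 2000 or 6603, leaving out WT replicate 1 or 3 gave 2346 or 2487, and all 16 genes named kept the call in each of these. With both viruses 1299 genes rose and 989 fell, and 1 gene changed in opposite directions, in cultures that share slides.

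The response to added Ankrd2 was read as Ad-Ankrd2 against Ad-GFP in each genotype and stage. In proliferating WT cells 3 genes passed. Ankrd2 rose by 10.83 ± 0.82 log2 (SE, 3 against 3 arrays, adjusted p = 9.61e-09), and Ren1 fell by 4.02 ± 0.34 (adjusted p = 4.4e-08), both with the same change when slide was a block. The third gene past the threshold, a transcript named only as ENSMUST00000097353 and so chosen after its values were seen, fell by 3.09 ± 0.26 (adjusted p = 4.4e-08). Interferon genes had 0 of 39 passing (0 adjusted over the list), with a median of -0.53 (adjusted p = 4.89e-09, and 0.979 with estimated correlation), -0.53 with slide as a block, -0.24 within slide 2 and -1.09 within slide 6. Antigen presentation genes had 0 of 18 passing (0 adjusted over the list), with a median of -0.36 (adjusted p = 1.92e-05, and 0.979 with estimated correlation), -0.36 with slide as a block, -0.19 within slide 2 and -0.68 within slide 6. Cytokine genes had a median of 0 (adjusted p = 0.986), -0.53 within slide 2 and 0.67 within slide 6, and no leukocyte gene of 20 passed (median 0.03).

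In proliferating WT cells these 3 genes were all that changed among 20027, 1 upward and 2 downward, and 9.82% of the tested genes were fully separated, where chance gives 10% for independent arrays and arrays of the same number here correlated at 0.51 to 0.79. The count was 16 with replicate as a block within the stage, 449 with slide as a block, 179 within slide 2 (2 arrays against 2), 261 within slide 6 (1 against 1), 5 after normexp correction and 7 with no filter on dim probes. Without Ad-Ankrd2 replicate 3 it was 5, without Ad-GFP replicate 3 it was 22, without both it was 36, and Ankrd2 and Ren1 kept the call in each of these.

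In fusing WT cells Mmp3, the matrix metalloproteinase stromelysin 1, fell with Ad-Ankrd2 by 2.46 ± 0.32 log2 (SE, 3 against 3 arrays, adjusted p = 0.00036), Il13ra2, the decoy receptor for interleukin 13, by 2.38 ± 0.34 (adjusted p = 0.00105), Il1rl1, the interleukin 33 receptor, by 2.2 ± 0.4 (adjusted p = 0.00869), and Rdh10, a retinol dehydrogenase, by 1.34 ± 0.21 (adjusted p = 0.00264). The mitochondrial superoxide dismutase gene Sod2 fell by 1.03 ± 0.2 (adjusted p = 0.016). Ankrd2 rose by 4.37 ± 0.82 (adjusted p = 0.0114), Megf6 by 1.76 ± 0.34 (adjusted p = 0.0146) and Plxna4, a semaphorin receptor, by 1.25 ± 0.26 (adjusted p = 0.0345). Of 37 cytokine genes 1 fell (9 adjusted over the list), Cxcl5 by 1.38 ± 0.25 (adjusted p = 0.00869). That list had a median of -0.96 (adjusted p = 9.66e-17, and 0.0666 with estimated correlation), -0.44 within slide 3 and -1.66 within slide 4. NF-kB genes had 0 of 23 passing (0 adjusted over the list) and a median of -0.21 (adjusted p = 0.00365, and 0.593 with estimated correlation), 0 within slide 3 and -0.67 within slide 4. Interferon genes had 0 of 38 passing (0 adjusted over the list) and a median of -0.57 (adjusted p = 1.17e-12, and 0.43 with estimated correlation), -0.39 within slide 3 and -1 within slide 4. Antigen presentation genes had 0 of 18 passing (1 fell adjusted over the list) and a median of -0.48 (adjusted p = 1.89e-09, and 0.331 with estimated correlation), -0.35 within slide 3 and -0.69 within slide 4. These medians are the same with slide as a block. Leukocyte genes had a median of 0.01 and 0 of 20 passed.

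Here 53 of 20106 genes changed, 11 upward and 42 downward, and 13.5% of the tested genes were fully separated, against 10% by chance. The count was 101 with replicate as a block within the stage, 694 with slide as a block, 467 within slide 3 (2 arrays against 2), 180 within slide 4 (1 against 1) and 0 in the 6 arrays alone. Without Ad-Ankrd2 replicate 1 or 2 it was 17 or 29, without Ad-GFP replicate 1 or 2 it was 12 or 13, and Mmp3, Il13ra2 and Rdh10 kept the call whichever array was left out. With the mean of a gene's probes Il1rl1 and Sod2 did not pass (-1.71, adjusted p = 0.145, and -0.54, adjusted p = 0.331). Within slide 4 Rdh10 (-0.56), Il1rl1 (-1.45) and Plxna4 (1.38) did not pass (adjusted p = 0.546, 0.255 and 0.0507).

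In differentiated WT cells Cxcl1 (chromosome 5, 91321845 to 91321904 of mm9) fell with Ad-Ankrd2 by 5.27 ± 0.44 log2 (SE, 3 against 3 arrays, adjusted p = 4.25e-08), and Cxcl5 (chromosome 5, 91190490 to 91190549) by 4.03 ± 0.25 (adjusted p = 1.12e-10). Acod1, the itaconate-producing enzyme of activated macrophages, fell by 3.59 ± 0.65, and the serum amyloid gene Saa1 by 3.17 ± 0.56 (adjusted p = 0.00333 and 0.00268). Ankrd2 rose by 6.11 ± 0.82 (adjusted p = 0.000101) and Plxna4 by 1.4 ± 0.26 (adjusted p = 0.00578). Of 37 cytokine genes 15 fell (22 adjusted over the list), among them Ccl2 by 2.91 ± 0.32 and Ccl7 by 2.19 ± 0.28. The list as a whole had a median of -1.9 (adjusted p = 9.55e-49, and 0.000204 with estimated correlation). Genes of NF-kB, the transcription factor that drives inflammatory genes, fell in 9 of 23 cases (15 adjusted over the list), Nfkbia by 2.26 ± 0.31 and Tnfaip2 by 1.51 ± 0.21. Across its members the median was -1.01 (adjusted p = 3.43e-34, and 0.000248 with estimated correlation). The lipopeptide receptor Tlr2 fell by 3.12 ± 0.33 and complement Cfb by 2.88 ± 0.35 (adjusted p = 3.27e-06 and 3.35e-05). Interferon genes fell in 1 of 39 cases (4 adjusted over the list), Irf1 by 1.35 ± 0.22. For the list the median was -0.59 (adjusted p = 2.47e-17, and 0.339 with estimated correlation). Antigen presentation genes fell in 2 of 18 cases (6 adjusted over the list), such as Psmb8 by 1.27 ± 0.21. The median over these genes was -0.59 (adjusted p = 2.47e-17, and 0.0523 with estimated correlation). None of 21 leukocyte genes passed (median -0.15), and 1 of 7 neutrophil granule genes fell (median -0.74). All 6 arrays are on slide 5, and these list medians are the same with slide as a block and within slide 5.

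Here 120 of 22238 genes changed, 10 upward and 110 downward, and 21.8% of the tested genes were fully separated, against 10% by chance. The count was 995 with slide as a block, 1040 within slide 5 and 549 in the 6 arrays alone. Without Ad-Ankrd2 replicate 1 it was 68, without Ad-GFP replicate 2 it was 78, without both replicate 3 arrays 66, and of the 14 genes named only Plxna4 lost the call, in the last of these (1.25, adjusted p = 0.0658). The labels give the Ad-GFP samples here an infection of 96 h and the Ad-Ankrd2 samples one of 20 h.

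In proliferating KO cells 3 genes passed as well. Ankrd2 rose by 7.35 ± 0.82 log2 (SE, 3 against 3 arrays, adjusted p = 3.82e-05). The interleukin 1 alpha gene Il1a fell by 4.04 ± 0.71 (at least 5.75-fold) and Mmp10 by 2.98 ± 0.53 (at least 4.44-fold), both with an adjusted p = 0.0485. Il1a was the 1 gene that fell of 38 cytokine genes (7 adjusted over the list), and the list had a median of -0.74 (adjusted p = 1.41e-21, and 0.0267 with estimated correlation), -0.74 with slide as a block, -0.84 within slide 1 and -0.49 within slide 6. NF-kB genes had 0 of 23 passing (0 adjusted over the list) and a median of -0.43 (adjusted p = 1.96e-10, and 0.112 with estimated correlation), -0.43 with slide as a block, -0.37 within slide 1 and -0.49 within slide 6. No leukocyte gene of 21 passed (median -0.07).

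These 3 genes, 1 upward and 2 downward (1 and 0 in the authors' table), were all that changed among 19869, and 7.46% of the tested genes were fully separated, against 10% by chance. The count was 12 with replicate as a block within the stage, 73 with slide as a block, 106 within slide 1 (2 arrays against 2), 28 within slide 6 (1 against 1), 7 with no filter on dim probes and 0 in the 6 arrays alone. It was 1, without Il1a and Mmp10, with one gene set for all comparisons, in the authors' table or with a mean-variance trend. Without any 1 Ad-Ankrd2 array it was 1, without Ad-GFP replicate 1 or 2 also 1, without Ad-GFP replicate 3 it was 22 and without both replicate 3 arrays 23. Ankrd2 kept the call in each of these but the 6 arrays alone and slide 6, and Il1a did not pass under normexp correction (-1.33, adjusted p = 0.622). Within slide 6 no named gene did: Ankrd2 changed by 5.46, Il1a by -1.55 and Mmp10 by -0.71 (adjusted p = 0.0798, 0.644 and 0.816).

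In fusing KO cells the cytokine, interferon and antigen presentation lists were lower with Ad-Ankrd2. Cxcl10, an interferon-induced chemokine, fell by 4.09 ± 0.77 log2 (SE, 3 against 3 arrays, adjusted p = 0.0106), Cxcl1 by 3.89 ± 0.44 and Ccl2 by 2.84 ± 0.32 (both adjusted p = 1.66e-05), Cxcl5 by 3.02 ± 0.25 (adjusted p = 8.39e-08) and Il6 by 2.94 ± 0.54 (adjusted p = 0.0094). Sod2 fell by 1.82 ± 0.2 and the death receptor gene Fas by 1.64 ± 0.28 (adjusted p = 1.66e-05 and 0.00356). Ankrd2 rose by 5.13 ± 0.82 (adjusted p = 0.00161) and Plxna4 by 2.1 ± 0.26 (adjusted p = 7.94e-05). Of 36 cytokine genes 9 fell (17 adjusted over the list), with a median of -1.32 (adjusted p = 1.64e-26, and 0.00791 with estimated correlation), -1.38 with slide as a block and -1.32 within slide 4. NF-kB genes fell in 4 of 23 cases (11 adjusted over the list), Tnfaip3 by 2.05 ± 0.39 and Nfkbia by 1.64 ± 0.31. The list as a whole had a median of -0.67 (adjusted p = 1.29e-13, and 0.0299 with estimated correlation), -0.81 with slide as a block and -0.77 within slide 4. Interferon genes fell in 5 of 39 cases (37 adjusted over the list), including the guanylate-binding protein genes Gbp2 by 2.13 ± 0.38 and Gbp6 by 1.98 ± 0.35 and Irf1 by 1.16 ± 0.22. Across its members the median was -1.47 (adjusted p = 9.37e-50, and 0.0278 with estimated correlation), -1.4 with slide as a block and -1.27 within slide 4. Antigen presentation genes fell in 2 of 18 cases (12 adjusted over the list), Psmb8 by 1.39 ± 0.21. For the list the median was -0.63 (adjusted p = 8e-18, and 0.0343 with estimated correlation), -0.63 with slide as a block and -0.61 within slide 4. None of 21 leukocyte genes passed (median 0.38, 0.2 with slide as a block and 0.15 within slide 4).

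Here 110 of 21815 genes changed, 12 upward and 98 downward (39 and 120 after normexp correction), and 14.9% of the tested genes were fully separated, against 10% by chance. The count was 608 with slide as a block, 535 within slide 4 (3 arrays against 2) and 23 in the 6 arrays alone. Without Ad-Ankrd2 replicate 2 or 3 it was 24 or 30, without Ad-GFP replicate 1, 2 or 3 it was 283, 29 or 23, and Cxcl10, Il6, Nfkbia, Tnfaip3, Gbp2, Gbp6 and Irf1 lost the call without some single array. Of the 6 arrays 3 lay nearest to another group: Ad-Ankrd2 replicate 1 to WT Ad-Ankrd2 replicate 3 (root mean square distance 0.43 log2), and Ad-GFP replicates 1 and 2 to KO Ad-Ankrd2 replicate 3 (0.39) and WT Ad-GFP replicate 3 (0.42). Deviations of arrays with the same number correlated at -0.62, -0.27 and -0.22. As the authors' table crosses Ad-Ankrd2 replicates 1 and 2, results by these numbers are uncertain. In the 2 genotypes 16 genes fell and 4 rose at the fusing stage in both.

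In differentiated KO cells 8 of 39 cytokine genes were lower with Ad-Ankrd2. Csf3, the granulocyte growth factor gene, fell by 5.26 ± 0.68 log2 (at least 11.7-fold; SE, 3 against 3 arrays, adjusted p = 0.000121), Il1a by 5.26 ± 0.71 (adjusted p = 0.000189), Il1b by 4.54 ± 0.7 (adjusted p = 0.000921), Cxcl2 by 4.61 ± 0.78 (adjusted p = 0.00242), Cxcl1 by 3.59 ± 0.44 (adjusted p = 7.17e-05), Il6 by 2.92 ± 0.54 (adjusted p = 0.00677) and Cxcl5 by 1.85 ± 0.25 (adjusted p = 0.000189). Slc7a11 fell by 2.33 ± 0.49 and Sod2 by 1.24 ± 0.2 (adjusted p = 0.0229 and 0.00159). Ankrd2 rose by 5.23 ± 0.82 (adjusted p = 0.000988), the chemokine receptor gene Ccr2 by 3.51 ± 0.64 (at least 5.55-fold), the stem cell receptor gene Lgr5 by 3.15 ± 0.6 (at least 2.95-fold) and the Notch target Hey1 by 1.52 ± 0.32 (adjusted p = 0.00525, 0.00919 and 0.0229). Of 39 cytokine genes 8 fell (16 adjusted over the list), with a median of -0.8 (adjusted p = 3.64e-24, and 0.0153 with estimated correlation), -0.74 with slide as a block and -0.72 within slide 2. NF-kB genes fell in 2 of 23 cases (10 adjusted over the list), Nfkb2 by 1.07 ± 0.24. The median over these genes was -0.7 (adjusted p = 3.55e-13, and 0.0467 with estimated correlation), -0.61 with slide as a block and -0.7 within slide 2. Interferon genes had 0 of 41 passing (0 adjusted over the list) and a median of 0.22 (adjusted p = 0.0172, and 0.938 with estimated correlation), 0.09 with slide as a block and 0.33 within slide 2. None of 21 leukocyte genes passed (median 0.07, and -0.07 within slide 2).

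In differentiated KO cells 96 of 19923 genes changed, 8 upward and 88 downward, and 13.8% of the tested genes were fully separated, against 10% by chance. The count was 178 with replicate as a block within the stage, 916 with slide as a block, 735 within slide 2 (2 arrays against 2) and 42 in the 6 arrays alone. Without Ad-Ankrd2 replicate 1 or 2 it was 45, without Ad-GFP replicate 1 it was 41, and without both replicate 3 arrays 44. Of the genes named, Nfkb2, Slc7a11, Ccr2, Lgr5 and Hey1 lost the call when some single array was left out. Il1a and Hey1 did not pass in the authors' table (adjusted p = 0.384 and 0.111), nor Hey1 under normexp correction (0.0957), nor Sod2 with the mean of its probes (0.0976), nor Lgr5 when all spots were kept (0.598). In the 2 genotypes, 29 genes fell and 1 rose at the differentiated stage in both. The 7 genes that fell with Ad-Ankrd2 in both genotypes at both the fusing and the differentiated stage were Adm, Cxcl5, Il13ra2, LOC632269, Mmp3, Pde4b and Sod2, singled out after the values were seen.

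**Figure D3:**
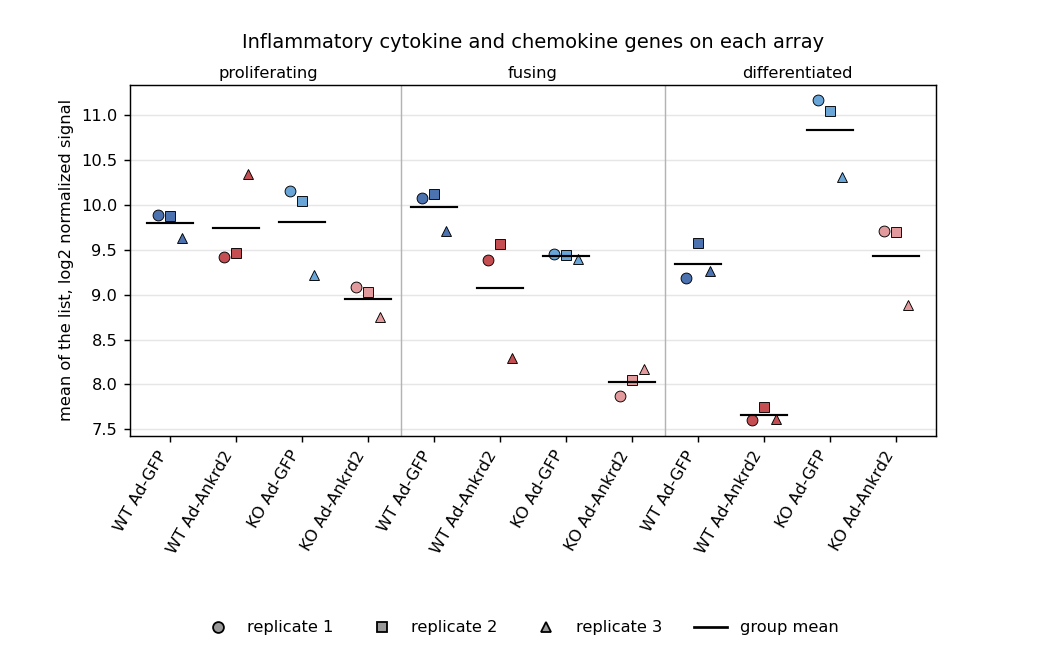
Mean log2 normalized signal (vertical axis) of inflammatory cytokine and chemokine genes on each of the 36 arrays, by genotype, virus and stage, with symbols for the replicate number and lines at the means of the groups.

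Whether the response to Ad-Ankrd2 differed between the genotypes was tested as a difference of differences at each stage. Cxcl5 was the 1 gene that passed, in differentiated cells, where its fall was smaller in KO than in WT by 2.18 ± 0.35 log2 (SE, 4 groups of 3 arrays, adjusted p = 0.0372). In proliferating cells limma found 0 of 20683 genes past the threshold (166 at an unadjusted p under 0.05), and in fusing cells 0 of 22015 (480). In differentiated cells it was 1 of 22553 (700). For Ankrd2 itself the differences were -3.48 ± 1.16, 0.75 ± 1.16 and -0.88 ± 1.16, none of which passed (adjusted p = 1 each). Cytokine genes had a median difference of -0.78 in proliferating cells with 0 of 40 passing (1 fell adjusted over the list, adjusted p = 8.05e-17, and 0.111 with estimated correlation), -0.78 with slide as a block and -1.27 within slide 6. In fusing cells it was -0.25 with 0 of 37 passing (4 fell adjusted over the list, adjusted p = 7.31e-06, and 0.678 with estimated correlation), -0.29 with slide as a block and 0.04 within slide 4. Cxcl5, Ccl2 and Cxcl1 differed there by -1.64 ± 0.35, -1.88 ± 0.46 and -2.53 ± 0.62, opposite in sign to Cxcl5 in differentiated cells, without passing (adjusted p = 0.647, 1 and 1). All 3 passed without WT Ad-Ankrd2 replicate 3, and Cxcl5 with slide as a block (-1.65, adjusted p = 0.012) but not within slide 4 (-0.95, adjusted p = 0.142). The cytokine median was 0.44 in differentiated cells with 1 of 40 passing (5 rose and 1 fell adjusted over the list, adjusted p = 0.000687, and 0.863 with estimated correlation), 0.5 with slide as a block. Interferon genes had a median difference of -0.94 in fusing cells with 0 of 39 passing (0 adjusted over the list, adjusted p = 1.71e-20, and 0.565 with estimated correlation), -0.8 with slide as a block and -0.26 within slide 4. In differentiated cells it was 0.91 with 0 of 41 passing (1 rose adjusted over the list, adjusted p = 3.59e-21, and 0.441 with estimated correlation), 0.84 with slide as a block.

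With slide as a block 3, 2 and 105 genes passed in proliferating, fusing and differentiated cells, and within slides 81 (slide 6) and 11 (slide 4) did. Leaving out 1 array moved the counts over 0 to 1 (1 without KO Ad-GFP replicate 2 or WT Ad-GFP replicate 3), 0 to 7 (7 without WT Ad-Ankrd2 replicate 3) and 0 to 8. The call for Cxcl5 was lost without some single array and after a 75th percentile shift (1.97, adjusted p = 0.319). The differentiated count in other settings is given below.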

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

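The tests of slide, cell type, limb origin, virus stock and array distances below were chosen after the results were seen, and the counts over other splits of the arrays were planned.

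The difference between KO and WT changed with the stage, which a direct test of that change picked out. From fusing to differentiated it changed for 2827 genes with Ad-GFP and 2326 with Ad-Ankrd2. From proliferating to fusing it changed for 16 genes with Ad-GFP and 2 with Ad-Ankrd2 (Sdc4 and Thnsl2). The response to Ad-Ankrd2 in WT cells changed from fusing to differentiated for 3 genes (Cxcl1, Cxcl5 and Wdr93) and from proliferating to fusing for 4 (Ankrd2, ENSMUST00000097353, LOC632269 and Ren1). In KO cells these numbers were 0 and 0 in limma (1500 and 465 at an unadjusted p under 0.05, the 465 below chance). The response also differed between the genotypes for 1 gene in differentiated cells, Cxcl5. Outside the genes, a negative control spot on WT Ad-GFP proliferating replicate 3 had a signal of 79158, where the brightest on any other array was 331.

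On the 6 WT differentiated arrays hindlimb position and neutrophil transcripts were low and adipocyte transcripts high. Against an effect of slide 5, its other arrays lay apart from them by 3.63 log2 in the hindlimb mean and 3.31 in the adipocyte mean. For neutrophil genes that gap was 0.95, to a fusing array, under the bound of 1 that was set, so slide stays open there. Within slide 5 their median in differentiated KO minus WT was 6.78, but from only 1 KO array. Another limb origin of these cells might be a cause and stays open: the median of 2 forelimb genes changed by -0.69 from fusing to differentiated, beside -4.15 for hindlimb genes. The loss of Ankrd2 in KO cells stays open too, since Ad-Ankrd2 changed the hindlimb genes of KO cells by a median of 0.11, and 20 h of the virus may be too short.

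Cytokine and NF-kB lists were lower with Ad-Ankrd2 in differentiated WT and in fusing and differentiated KO cells, also with an estimated correlation. In fusing WT cells both were called, but not with an estimated correlation (adjusted p = 0.0666 and 0.593). Fewer leukocytes are argued against: the lowest median of the leukocyte genes was -0.15, none of them passed, and the cytokine medians (-0.96, -1.9, -1.32 and -0.8) lay below the lower quartiles of the leukocyte genes (-0.14, -0.49, 0.05 and -0.21). Slide is argued against for cytokine genes, since their highest median within any slide was -0.44, and stays open for NF-kB genes in fusing WT cells (0 within slide 3). A difference between the virus stocks in dose or innate stimulation stays open, because the interferon list had medians of -0.57, -0.59, -1.47 and 0.22. An effect of Ankrd2 is not told apart from it, as no second stock was measured. In differentiated WT cells labelled infection time (96 h for Ad-GFP, 20 h for Ad-Ankrd2) stays open.

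In most groups 2 of the 3 arrays lay close together and 1 apart. In 9 of 12 groups the close pair was replicates 1 and 2. Slide is argued against in KO Ad-Ankrd2 fusing, where all 3 arrays share a slide and the second smallest distance was 2.21 times the smallest. In the other 2 groups on 1 slide, both WT differentiated, it was 1.23 and 1.15 times, so slide stays open there. In the 9 groups on 2 slides, 8 had their close pair on 1 slide, so slide stays open for them too. No biological explanation was tested.

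The 6 arrays of a comparison can be split in 10 ways, too few for a share under 0.05. The real count and the highest of the other splits were 3163 and 444 for fusing against proliferating, and 5006 and 0 for differentiated against fusing. For KO against WT with Ad-GFP they were 153 and 167, 8 and 608, and 3805 and 6 in proliferating, fusing and differentiated cells, and with Ad-Ankrd2 64 and 0, 29 and 1, and 4121 and 1. For Ad-Ankrd2 against Ad-GFP they were 3 and 269, 53 and 1, and 120 and 0 in WT cells, and 3 and 451, 110 and 1312, and 96 and 356 in KO cells. The number of splits with as many genes, the real one included, was 2, 3 and 1 for KO against WT with Ad-GFP, 4, 1 and 1 for the virus in WT cells, 3, 2 and 2 in KO cells, and 1 in each of the other 5.

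Some of these other splits follow slides. For KO against WT with Ad-GFP in proliferating cells the split of 167 genes set the 2 slide 1 arrays and 1 slide 6 array against the rest. In fusing cells the split of 608 put the 2 slide 3 arrays with 1 of slide 4. The 608, 269, 451, 1312 and 356 genes are several times the real counts and point to a structure of the samples. If arrays of the same replicate number are taken as pairs, the real split parts all 3 pairs, and the split of 167 does so too. The split of 269 put 3 slide 2 arrays together, that of 451 3 slide 1 arrays and that of 356 3 slide 2 arrays, so each keeps a pair together. Within slides the real counts there were 179 (slide 2), 106 (slide 1) and 735 (slide 2). The split of 1312 set KO Ad-Ankrd2 fusing replicate 1 and KO Ad-GFP fusing replicates 2 and 3 against the rest. The replicate 1 arrays of both groups lay nearest to another group.

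For the differences of differences, 100 splits were drawn. In proliferating and fusing cells the real count is 0, so all 100 give as many and nothing is decided. In differentiated cells 21 gave as many as the real 1, so chance is not excluded. The highest others were 2582, 1977 and 280.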

How the results depend on the processing

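The replicate block within the stage, the joint removal of replicate 3 arrays and the values within slides were chosen after seeing the data. Of 180 genes named, 168 were past the threshold, and of these 92 kept direction and call in every planned setting with no array left out. Direction held for 167 in every setting, and 45 lost the call when 1 array was left out. Of 140 list calls, 14 held with an estimated correlation. The scan date separates the arrays exactly as slide does, so it was not run on its own. The series table lacks values for dim spots, so 160 of the genes have a value there. Signal over background limits the genes given as at least a fold. Where no reason is given below, the cause was not tested.

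In counts of changed genes, comparisons are named by stage and kind. After a 75th percentile shift KO against WT gave 100 (Ad-GFP, proliferating), 5 (Ad-GFP, fusing) and 40 (Ad-Ankrd2, proliferating), and the differences of differences 1 (fusing) and 0 (differentiated). Normexp correction gave 246, 18, 153 and 46 for KO against WT (Ad-GFP proliferating and fusing, Ad-Ankrd2 proliferating and fusing), 5 for Ad-Ankrd2 in proliferating WT cells and 2 for the difference of differences in proliferating cells. The authors' table gave 14 and 102 for KO against WT (Ad-GFP fusing, Ad-Ankrd2 proliferating), 1 for Ad-Ankrd2 in proliferating KO cells, and 1 and 2 for the differences of differences (fusing, differentiated). With no filter on dim probes KO against WT in fusing Ad-GFP cells gave 32, Ad-Ankrd2 in proliferating cells 7 (WT) and 7 (KO), and the difference of differences in differentiated cells 3. One gene set for all comparisons gave 1 for Ad-Ankrd2 in proliferating KO cells, since more genes were tested, and a mean-variance trend gave 1 there. The mean of a gene's probes gave 16 for KO against WT in fusing Ad-GFP cells and 2 for the difference of differences in differentiated cells. Culture as a random block gave 15 for KO against WT in fusing Ad-GFP cells. With only the arrays compared, where fewer arrays estimate the spread, the counts were 361 for fusing against proliferating, 0, 0, 0 and 1 for KO against WT (Ad-GFP proliferating and fusing, Ad-Ankrd2 proliferating and fusing), 0 and 549 for Ad-Ankrd2 in fusing and differentiated WT cells, 0, 23 and 42 in proliferating, fusing and differentiated KO cells, and 7 for the difference of differences in differentiated cells. With at least 2-fold, a stricter threshold, they were 1336 and 2153 for the 2 steps, and 69, 1724, 42 and 1777 for KO against WT (Ad-GFP proliferating and differentiated, Ad-Ankrd2 proliferating and differentiated).

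With the replicate block the counts were 232, 80 and 98 for KO against WT (Ad-GFP proliferating and fusing, Ad-Ankrd2 proliferating) and 2 for the difference of differences in differentiated cells, and the block changed the call of no gene named. The numbers pair the arrays in 6 comparisons. In the others they are only shared, and every array correlated best with its own number in 1 of these 8, fusing against proliferating. As a block within the stage they gave 672, 99 and 502 for the same 3, 16, 101 and 213 for Ad-Ankrd2 in proliferating, fusing and differentiated WT cells, 12, 197 and 178 in KO cells, and 1 for the difference of differences in fusing cells.

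With slide as a block the counts were 1520 for differentiated against fusing, 2622 and 56 for KO against WT with Ad-GFP (proliferating, fusing), 3566 and 84 with Ad-Ankrd2, 449, 694 and 995 for Ad-Ankrd2 in proliferating, fusing and differentiated WT cells, 73, 608 and 916 in KO cells, and 3, 2 and 105 for the differences of differences. Within slide 6 KO against WT in proliferating cells gave 1705 (Ad-GFP) and 2195 (Ad-Ankrd2), Ad-Ankrd2 gave 261 (WT) and 28 (KO), and their difference 81. Within slide 4 the fusing comparisons gave 58, 48, 180, 535 and 11 in the same order. Slide 2 gave 179 for Ad-Ankrd2 in proliferating WT and 735 in differentiated KO cells, slide 3 gave 467 in fusing WT, slide 5 gave 1040 in differentiated WT and slide 1 gave 106 in proliferating KO cells. A lone array on a slide is assumed to vary like the other groups.

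Without both replicate 3 arrays the counts were 5836 for fusing against proliferating, 2369 and 878 for KO against WT in proliferating cells (Ad-GFP, Ad-Ankrd2), 36 and 66 for Ad-Ankrd2 in proliferating and differentiated WT cells, 23 and 44 in KO cells, and 0 for the difference of differences in differentiated cells. Of the genes named 10 then lost the call. Leaving out 1 array gave 1274 to 4505 and 2540 to 5967 for the 2 steps. For KO against WT it gave 9 to 1248, 1 to 704 and 1910 to 4026 with Ad-GFP, and 12 to 223, 3 to 788 and 2000 to 6603 with Ad-Ankrd2. For Ad-Ankrd2 it gave 3 to 22, 12 to 49 and 68 to 96 in WT, and 1 to 22, 23 to 283 and 41 to 114 in KO cells. For the differences of differences it gave 0 to 1, 0 to 7 and 0 to 8.

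Some directions reversed. Ankrd2 in KO against WT with Ad-GFP was 0 (normexp), -0.41 (slide as a block), -0.08 (without KO replicate 3), -0.07 (without WT replicate 2) and -0.04 (without both replicate 3 arrays) in differentiated cells, up to 0.19 without another array, and -0.55 (slide as a block) and -0.24 (within slide 6) in proliferating cells. Its difference of differences in fusing cells was -0.45 (without KO Ad-Ankrd2 replicate 1) to 1.47 with 1 array left out, and -1.2 (within slide 4), where the cytokine list was 0.04. In fusing KO against WT cells with Ad-GFP the cell cycle list was 0.44 with slide as a block and 0.57 within slide 4, and the cholesterol list -0.2 and -0.32. With Ad-Ankrd2 the cholesterol list was -0.21 and -0.14. Col1a1 in proliferating Ad-GFP cells was -0.04 within slide 6. The leukocyte list with Ad-Ankrd2 in differentiated KO cells was -0.26 without Ad-Ankrd2 replicate 1 or 2 and -0.39 without Ad-GFP replicate 3, and up to 0.52 without another array.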

Other observations

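The tests on recurring genes here were chosen after the values were seen. Of the genes that differed between KO and WT at the proliferating and fusing stages, 30 passed in the same direction in at least 2 of these 4 comparisons, 15 of them higher and 15 lower in KO. Among them 3 pairs lay within 0.5 Mb of each other: Dcun1d1 and Acad9 on chromosome 3, Khk and Abhd1 on chromosome 5, and Pycr1 and Slc16a3 on chromosome 11 (mm9). In 10000 random sets of 30 genes the mean number of such pairs was 0.35 (permutation p = 0.0051). Strain haplotypes carried with the knockout predict neighbouring genes, and the mixed strain background of the mice makes this a possible explanation. The flank of the knockout allele stays open: 3 of 205 genes within 10 Mb of Ankrd2 were called (1.46%) against 215 of 22201 elsewhere (0.968%, Fisher's exact p = 0.455).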
